A study of Mus musculus with 2 samples.

How the data were processed

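Single-cell RNA sequencing was carried out on cells from enzymatically digested aortas of mice fed a western diet for 12 weeks. There were 2 libraries, 1 per genotype: Apoe knockout (Apoe_KO) and an inducible endothelial double knockout on the Apoe knockout background (EC-iDKO_Apoe_KO, below the double knockout). The number of mice behind each library and the library dates were not given in the sources used here. The protocol text names 10x droplets with 3' tags and CD31 microbeads, while the cell type label gives all cells, so the endothelial share can depend on the beads.

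The deposited count table holds counts, that is UMIs per cell and gene, and its cell totals equal those of the deposited metadata table. The submitters' processing notes name Cell Ranger and Seurat with the mm10 build; their versions and the gene annotation were not given in the sources used here. The mitochondrial ratio that the authors computed per cell is a fraction, with values up to 20.0%. The deposited class and cluster number of each cell are of another kind ("other"), names and numbers that the authors assigned after integrating the libraries. The deposited cells had already been filtered, with no cell under 500 UMIs before the gene filter. Of the 10345 deposited cell entries, 4856 were of the Apoe knockout library and held each of 2428 barcodes in 2 copies with identical counts. Each barcode was counted once, which left 2428 Apoe knockout and 5489 double knockout cells and 14714 genes.

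The Apoe knockout library held 13304762 UMIs with a median of 3770 per cell, and the double knockout library 6853185 with a median of 769. Cells are not replicates. With 1 library per genotype, no p-value, standard error or count of changed genes was made from cells, and every comparison is a description of these 2 libraries. UMIs were summed over the cells of a population and scaled to a total of 1000000 UMIs (CPM). Sums carry exact Poisson intervals, ratios exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, at the 95% level. These intervals cover counting error only, not the difference between mice, dissections or library preparations. A ratio against a count of 0 was computed against a floor of 3 UMIs over the population and is given as a lower bound. A list median that such genes set is given as a bound too, at or below or at least the value, without an interval.

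Genes were called higher or lower by a rule of size: a ratio of at least 1.5 in either direction with an interval that did not hold 1. The named genes of the endothelial population were the 12 with the highest and the 12 with the lowest ratio that met this rule, and in each other population the 6 highest and 6 lowest. They needed at least 100 UMIs over both libraries in the population and a mean of at least 50 CPM. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, predicted and sex-linked genes were left out of that ranking. From each gene list that is described, up to 4 members with the largest ratio are named, out of those with at least 20 UMIs. Epn1 and Epn2 were named in every case. The ranking of genes with a count of 0 by their ratio to the floor was settled after the data were seen. A few other genes, such as Cfd, Car3, Adipoq, Sema3g and Cd74, were chosen after their values were seen.

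The tables hold 33 gene sets and 22 lists of cell type markers, fixed before the data were examined. For each set in each population, the median log2 CPM ratio over its members with at least 20 UMIs was computed, with an interval from 1000 Poisson draws. Its percentile among 10000 random lists of the same size and similar expression was also computed, as a description and not as a test.

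The comparisons had been planned on the deposited classes. After the data were seen, the populations were narrowed, which departs from the plan. Of the EC class, cluster 9 was kept. Cluster 20 led with the leukocyte genes Ccl5, Il7r, Ptprc and Cd52, and cluster 19 had 9 Apoe knockout cells, under the minimum of 50. Cluster 15 was left out of the SMC class, since its leading genes held 3 adipocyte markers. It made up 3.29% of the Apoe knockout and 1.46% of the double knockout cells. Cluster 19 made up 0.371% and 1.22%, and cluster 20 made up 1.07% and 0.492%. Within the immune/inflam class, cluster 13 was kept. Clusters 7, 8 and 10 of the modEC class were compared by number, because their leading genes were markers of other cell types. Clusters 1, 5 and 18 of the SMC class were kept although each had 1 marker of another type among its 10 leading genes (Hbb-bs, Rgs5 and Col2a1).

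The rule of size was tested on simulated data made by drawing both libraries from 1 profile at the observed depths, with 50 genes changed at each of 4 folds. In cluster 9, with 776 genes of at least 100 UMIs, it recovered 96% of the genes changed 2-fold in either direction and all of those changed 4-fold. It called 5.03% of the unchanged genes. Their median log2 ratio was -0.195, since the changed genes shifted the totals of so small a set. The part of low counts in these calls was not separated. In smooth muscle, with 8924 genes, it recovered 96% at a fold of 0.5, all at the other folds, and called 0.527% of the unchanged genes. The draws were Poisson and held counting error only. The rates thus do not cover differences between mice, preparations or mixes of cells.

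Alternatives planned before the data were examined were median-ratio scaling, each cell weighted equally, cells with at least 1000 UMIs and under 10% mitochondrial UMIs, and thinning of each cell to 1000 UMIs. Others were a minimum of 100 UMIs per list gene, a minimum of 20 UMIs per ranked gene, a ratio of 2 in the rule of size, mitochondrial and ribosomal genes left out of the total, and genes below 10% of their level in another class left out. A new clustering per library (30 principal components, 15 neighbours, Leiden at resolution 1) was named from at least 3 fixed markers. Chosen after seeing the data were the subtraction of a smooth muscle profile, scaled by the contractile genes, the whole deposited classes, and smooth muscle without clusters 1, 5 and 18. The alternatives for the marker genes of the whole libraries and the keeping of both copies of each cell were also added then. Scrublet, run per library, marked 4 of 2428 and 0 of 5489 cells. So few calls were taken as a failure of the caller, and no doublets were removed. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9. Gene positions are those of GENCODE M21 on GRCm38.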

Results

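Digested aortas of western diet-fed mice were compared between 1 Apoe knockout library and 1 library of an inducible endothelial double knockout on the same Apoe knockout background. Apoe knockout mice develop atherosclerosis on this diet. The question, from knowledge of the line, was how endothelial loss of the epsins Epn1 and Epn2, adaptors of clathrin-mediated endocytosis, bears on the passage of endothelial cells toward a mesenchymal state. There were no replicates, so intervals cover counting error only and the terms higher and lower describe these 2 libraries.

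The libraries differed in depth. The median Apoe knockout cell had 3770 UMIs and 1662 genes, and the median double knockout cell 769 UMIs and 499 genes, a ratio of 4.90 between the median UMI counts. At least 1000 UMIs were reached by 94.6% of the 2428 Apoe knockout cells and 34.0% of the 5489 double knockout cells. Among cells with at least 1000 UMIs and under 10% mitochondrial UMIs, the ratio of the medians was 2.56. The median mitochondrial share was 4.80% and 3.99%. Both libraries expressed the Y-linked gene Ddx3y, with 1651 and 971 UMIs, and almost no Xist, with 8 and 2 UMIs.

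Epn1 was low in the deposited EC class of both libraries, with 14 UMIs in the Apoe knockout and 6 in the double knockout. The ratio of the CPM values, 39.1 and 15.6, was 0.40 with an interval of 0.13 to 1.11, so a difference was not detectable at this depth. Epn2 had 23 and 32 UMIs in the same class, at 64.3 and 83.3 CPM, a ratio of 1.30 (0.74 to 2.32). In smooth muscle, Epn1 stood at 29.5 and 27.6 CPM and Epn2 at 81.2 and 110 CPM. On GRCm38, Epn1 lies on chromosome 7 from 5080235 to 5098178 and Epn2 on chromosome 11 from 61517249 to 61579687. Tags from the 3' end of a transcript do not read a deleted exon upstream, so these counts are no measure of the deletion.

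Cartilage-like and macrophage transcripts were far lower over the whole double knockout library, and fat cell transcripts were found in that library almost alone. Ibsp, a bone matrix sialoprotein, was 272-fold lower (181 to 429) in the double knockout, with 12130 UMIs in the Apoe knockout and 23 in the double knockout. Col2a1, the collagen of cartilage, had 9290 and 2 UMIs, and the cartilage protein gene Chad had 2079 and 8. C1qa, a complement gene of macrophages, was 36.2-fold lower (26.1 to 51.9), and Cd74, the class II invariant chain, was 38.5-fold lower (31.2 to 48.2). The macrophage gene Adgre1 had 180 UMIs in the Apoe knockout and 0 in the double knockout, at least 30.9-fold lower. Cfd, the adipocyte protease adipsin, had 0 UMIs in the Apoe knockout and 3020 in the double knockout, at least 1954-fold higher. The fat cell genes Car3 and Adipoq had 0 and 1 UMIs in the Apoe knockout and 1346 and 163 in the double knockout.

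Over whole lists of markers, the median log2 ratio of the double knockout over the Apoe knockout was at or below -2.21 for 7 chondrocyte-like genes, -4.09 for 11 macrophage genes and -2.85 for 7 T cell genes, bounds set by genes with 0 UMIs in the double knockout. It was -2.66 for 8 foamy macrophage genes, -2.24 for 6 cycling genes, -1.36 for 10 fibroblast genes and -1.01 for 10 modulated smooth muscle genes. The adipocyte median was at least 7.21 over 4 genes, 2 of them with 0 UMIs in the Apoe knockout. The median was 4.24 for 3 erythroid genes and 1.58 for 12 endothelial genes. The 9 contractile smooth muscle genes stood at 0.19 and 6 pericyte genes at 0.02. In cells with at least 2000 UMIs, chosen after seeing the data, the T cell median was at or below -0.72 and the endothelial median 0.58. Each cell thinned to 1000 UMIs gave an adipocyte median of at least 3.73 and an endothelial median of 0.88. Pecam1, an endothelial adhesion molecule, stood at 78.5 and 177 CPM, and the CD31 beads of the protocol select on its product.

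**Figure D1:**
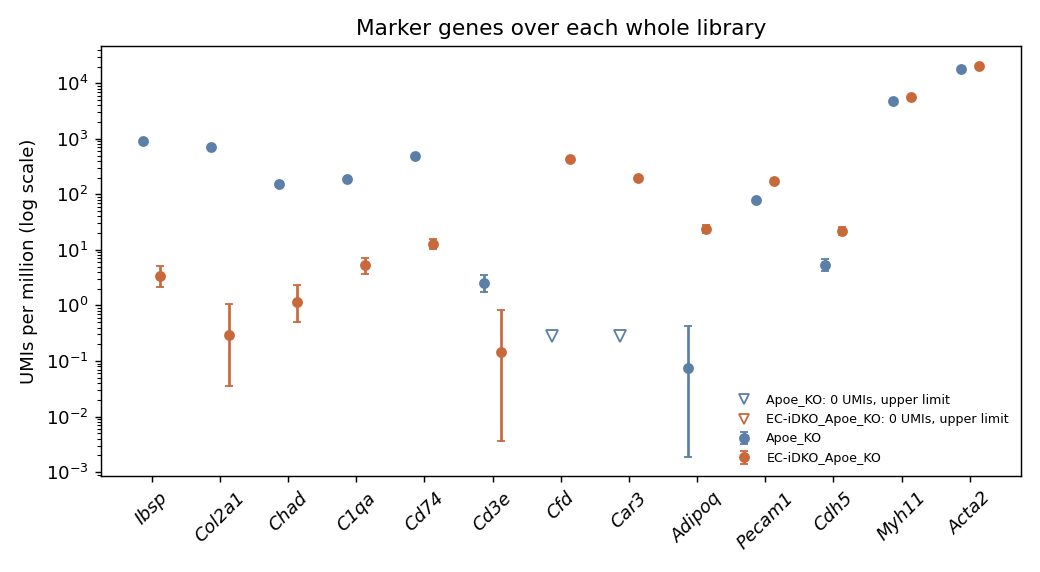
CPM of marker genes (vertical axis, log scale) over all cells of each library, with exact 95% Poisson intervals as bars and open triangles at the upper limit for 0 UMIs. Cartilage and macrophage genes (Ibsp, Col2a1, Chad, C1qa, Cd74) lay lower in the double knockout, the fat cell genes Cfd, Car3 and Adipoq higher, and Myh11 and Acta2 at similar levels.

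Smooth muscle cells were the most frequent class in both libraries and took a larger share in the double knockout. The SMC class made up 63.3% (61.3 to 65.2) of the Apoe knockout cells and 80.3% (79.2 to 81.3) of the double knockout cells. The modEC class made up 20.4% (18.8 to 22.0) and 10.7% (9.87 to 11.5). Its compared clusters went both ways: of all cells, cluster 7 made up 4.20% and 7.20%, cluster 8 7.58% and 2.70%, and cluster 10 6.88% and 1.71%. The immune/inflam class held 6.88% (5.90 to 7.96) and 1.11% (0.851 to 1.43), and the fibroblast class 4.08% (3.33 to 4.94) and 1.00% (0.756 to 1.30). The EC class held 5.40% (4.53 to 6.37) and 6.92% (6.27 to 7.63), and the beads can set this share. Among cells with at least 1000 UMIs and under 10% mitochondrial UMIs, the EC shares were 6.31% and 6.25%, which turned the direction. The fibroblast shares in those cells were 3.87% and 2.37%. In a new clustering of each library, 282 double knockout cells formed a cluster named fibroblast-like, with modEC as their most common deposited class. No Apoe knockout cluster took that name. Apoe knockout clusters with the shared marker Lum were named modulated smooth muscle. In deposited cluster 8, Dcn stood at 8707 CPM in the Apoe knockout and 3648 in the double knockout, and Lum at 6122 and 1406. The name thus does not place fibroblast-like cells in the double knockout alone.

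**Figure D2:**
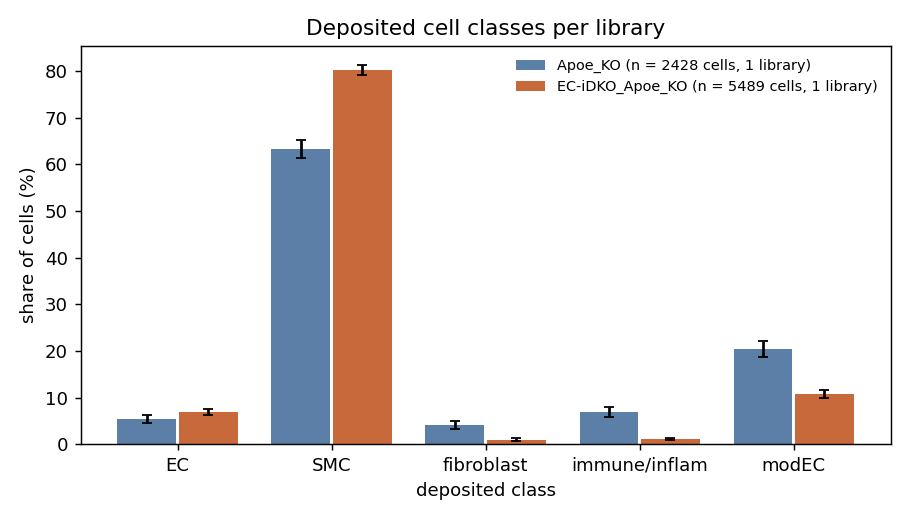
Share of cells (%) in each deposited class (horizontal axis) for the 2428 Apoe knockout and 5489 double knockout cells, with exact 95% binomial intervals. The SMC bars stand at 63.3% and 80.3%, and the modEC bars at 20.4% and 10.7%.

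Endothelial cells of cluster 9 had higher endothelial identity genes and lower collagen and small proteoglycan genes in the double knockout. The comparison took 96 Apoe knockout and 287 double knockout cells. Of 13 measured identity genes, 5 were higher and 0 lower, with a median log2 ratio of 0.37 (0.21 to 0.90), at the 98.3 percentile of random lists. The tight junction gene Cldn5 was 2.94-fold higher (1.98 to 4.46), the clotting factor carrier Vwf 2.45-fold (1.66 to 3.66), the secreted factor Egfl7 2.31-fold (1.64 to 3.28) and the receptor gene Tie1 1.91-fold (1.08 to 3.48). Of 14 mesenchymal transition genes, 0 were higher and 6 lower, with a median of -0.53 (-0.73 to -0.34), at the 0.29 percentile. The fibrillar collagens Col1a1, Col3a1 and Col1a2 were 5.67-fold (4.36 to 7.47), 3.15-fold (2.47 to 4.03) and 2.56-fold lower (2.07 to 3.19), and the membrane protease Mmp14 had 27 UMIs in the Apoe knockout and 2 in the double knockout.

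The identity median of cluster 9 moved with the setting. It was 1.17 in cells with at least 1000 UMIs and under 10% mitochondrial UMIs, 1.05 with cells thinned to 1000 UMIs, and 1.05 for members with at least 100 UMIs. Over the whole deposited EC class it was 1.13. That class adds cluster 19, with 9 Apoe knockout and 67 double knockout cells, and cluster 20, with 25 and 26. Its mix of cells thus differed between libraries. After subtraction of a smooth muscle profile, the identity median of cluster 9 was 0.19. The mesenchymal median was -1.81 after that subtraction and was below 0 in each of the settings run. The subtraction was scaled by the contractile genes, and Acta2, Tagln and Cnn1 are on both the contractile and the mesenchymal list. The medians of these 2 lists after subtraction thus follow in part from the procedure. RNA of smooth muscle was abundant in these cells: the contractile genes stood at a median of 61.4% of their smooth muscle level in the Apoe knockout cells and 55.4% in the double knockout cells. Their median log2 ratio in cluster 9 was -0.18, and 1.01 after the subtraction.

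Shares of cells with a mesenchymal UMI were compared after thinning to 1000 UMIs, which left 94 and 59 cells and left out 2 and 228. Before thinning, the median depth of the cells kept was 2160 and 1357 UMIs. Col1a1 was seen in 71.3% (61.0 to 80.1) of the Apoe knockout and 23.7% (13.6 to 36.6) of the double knockout cells, and Col1a2 in 63.8% (53.3 to 73.5) and 28.8% (17.8 to 42.1). For background, the Apoe knockout cells of the leukocyte-like cluster 20, with a median of 2201 UMIs, showed Col1a1 in 12.5% and Col1a2 in 20.8% of 24 cells. The macrophages of cluster 13 in that library, with a median of 4783 UMIs, showed Col1a1 in 36.0% and Col1a2 in 35.3%. In the double knockout, cluster 20 showed Col1a1 in 18.2% of 11 cells and cluster 13 in 40.0% of 15 cells. Their median depths were 1584 and 1174 UMIs. The T cell genes Cd3e and Trac had 29 UMIs each in Apoe knockout cluster 20 and 0 in double knockout cluster 20. Double knockout cluster 20 was thus not shown to hold leukocytes. Smooth muscle showed Col1a1 in 47.3% of Apoe knockout and 34.1% of double knockout cells, and Col1a2 in 57.9% and 45.4%. Apoe knockout cluster 9 lay above clusters 20 and 13 of its library for both genes, but its Col1a2 interval held the smooth muscle value. Double knockout cluster 9 lay below smooth muscle and cluster 13 for Col1a1, with intervals that overlapped. Contractile genes stood at 24.5% and 65.9% of their smooth muscle level in cluster 13. That background thus held unlike amounts of smooth muscle RNA between libraries. Acta2 was seen in 98.9% and 84.7%, Tagln in 94.7% and 86.4%, and Vim in 97.9% and 93.2% of cluster 9 cells. Their shares in Apoe knockout cluster 20 were 100%, 87.5% and 83.3%; shares so near their ceiling cannot separate cells from background. In UMIs per 1000, cluster 9 had 13.99 and 12.2 for Acta2, 9.28 and 9.29 for Tagln, and 6.48 and 5.69 for Vim. Cluster 20 had 4.88 and 8.55, 2.62 and 7.91, and 1.42 and 5.91, and cluster 13 had 7.41 and 15.3, 4.04 and 16.3, and 4.58 and 6.67. Smooth muscle had 21.7 and 23.2, 12.4 and 16.6, and 6.73 and 7.85. Apoe knockout cluster 9 thus lay above clusters 20 and 13 of its library for the 3 genes, and double knockout cluster 9 between them or, for Vim, below both. Fn1, the matrix glycoprotein fibronectin, was seen in 78.7% and 74.6% of cluster 9 cells, against 20.8% and 27.3% in cluster 20, 45.3% and 53.3% in cluster 13, and 71.5% and 70.9% in smooth muscle. Without thinning, the double knockout share was lower by more for Col1a1, at -63.5 percentage points, for Col1a2, at -54.1, and for Fn1, at -33.1.

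Among all ranked genes of cluster 9, the surface antigens Ly6a and Ly6c1 were the highest, at 5.62-fold (3.88 to 8.36) and 4.29-fold (2.64 to 7.29). Ly6a is also on the modulated smooth muscle list and stood at 244 and 186 CPM in cluster 8, against 127 and 715 in cluster 9. Next came Lars2, a mitochondrial leucyl-tRNA synthetase, at 4.19-fold, the interferon-induced Ifitm3 at 2.84-fold and the angiotensin-converting enzyme gene Ace at 2.82-fold. Ier3 and Ier2 were 2.76-fold and 2.71-fold higher, within an immediate early list whose median was -0.37 (-0.58 to -0.15), with 3 of 14 members higher and 5 lower, Egr1 at -0.92 among them. Also higher were the ER disulphide isomerase Pdia3, at 2.66-fold, and the proteoglycan serglycin, Srgn, at 2.44-fold. Lyz2, lysozyme of myeloid cells, had 320 UMIs in the Apoe knockout and 0 in the double knockout, at least 101-fold lower. It stood at 4885 CPM in the Apoe knockout macrophages of cluster 13, against 1199 CPM in cluster 9. In the Apoe knockout SMC, fibroblast and modEC classes it stood at 46.4, 16.6 and 114 CPM. Macrophages, or doublets with them, were thus not excluded in Apoe knockout cluster 9, and no doublets were removed. Their RNA lowers the CPM of identity genes and raises that of cytokines, so part of those differences can come from it.

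Lum and Dcn, small proteoglycans of fibrous matrix, were 33.0-fold (13.9 to 103) and 12.3-fold lower (8.11 to 19.5) in double knockout cluster 9. In the Apoe knockout, Dcn stood at 1172 CPM in cluster 9 and 8707 CPM in cluster 8, and Lum at 655 and 6122 CPM. Col1a1 stood at 1487 and 8051 CPM. The co-chaperone Dnajb1 was 4.58-fold lower, the chaperones Hspa1b and Hspa1a 3.29-fold and 3.16-fold, the chemokine Cxcl2 3.47-fold and the actin-binding Tmsb10 2.47-fold. Ctla2a, a protease inhibitor gene, was 11.2-fold lower (7.10 to 18.7), but its log2 ratio was 0.58 in cells thinned to 1000 UMIs. Cxcl2 stood at 5471 CPM in Apoe knockout cluster 13.

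**Figure D3:**
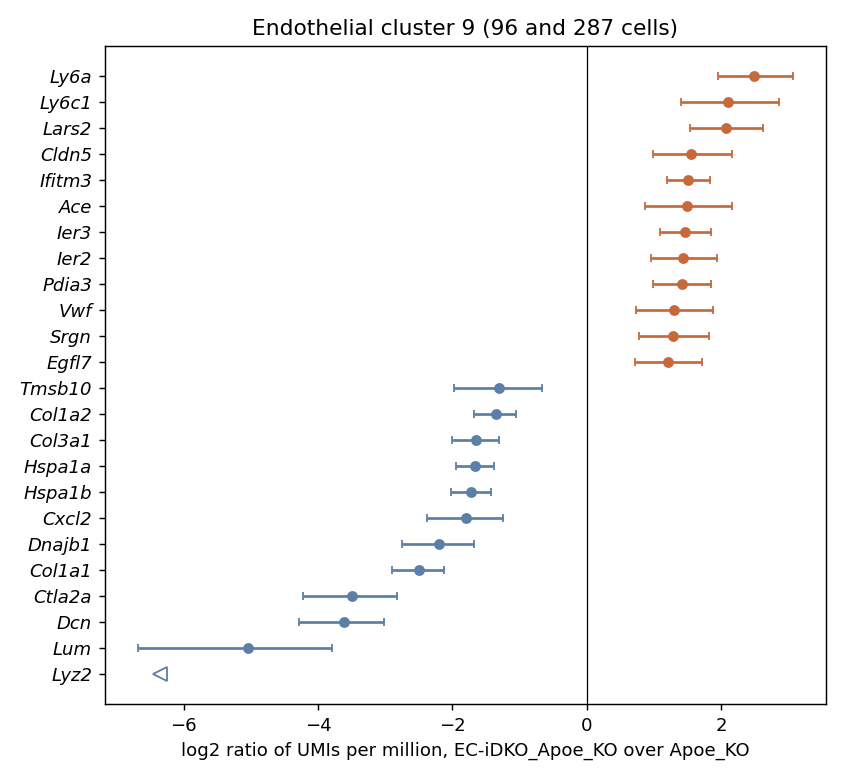
Log2 ratio of CPM values (horizontal axis), double knockout over Apoe knockout, for the 24 ranked genes of endothelial cluster 9, with exact 95% counting intervals. The open triangle marks the upper limit for Lyz2, which had 0 UMIs in the double knockout; Ly6a was the highest at 2.49 and Lum the lowest of those with counts in both libraries at -5.04.

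Inflammatory cytokines were lower in double knockout cluster 9, with a median of -1.69 (-2.55 to -1.15) and 6 of 8 members lower. Ccl4, Ccl2 and Tnf had 47, 34 and 31 UMIs in the Apoe knockout and 1, 0 and 0 in the double knockout. Macrophage markers in the same cells had a median at or below -4.50, with 3 of 4 lower and 0 higher, and foamy macrophage markers -1.29 (-2.08 to -0.61), with 3 of 5 lower. The cytokine difference was thus not separated from macrophage RNA in the Apoe knockout cells. The adhesion receptors Icam1 and Vcam1 were 2.27-fold (1.60 to 3.26) and 2.11-fold higher (1.62 to 2.76), within a leukocyte adhesion list whose median was -0.36 (-0.75 to 0.17). The interferon response list had 3 measured members and a median of 1.14 (0.27 to 1.67), led by Ifitm3 and Bst2. Extracellular matrix genes had a median of -0.53 (-0.94 to -0.41), with 7 of 18 lower, beside fibroblast markers at -2.50 (-2.89 to -2.15), with 4 of 5 lower. Cholesterol efflux genes stood at -0.69 (-1.11 to -0.24), led by the phospholipid transfer protein gene Pltp. The cartilage list had a median at or below -2.14, but 0.64 for its 3 members with at least 100 UMIs.

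In the signalling lists tied to the question, the cluster 9 median was -0.09 (-0.49 to 0.42) for FGF signalling, 0.09 (-0.27 to 0.38) for TGF-beta signalling, 0.36 (-0.33 to 0.75) for VEGF signalling and 0.20 (-0.28 to 0.64) for Notch signalling. The epsin and clathrin list stood at 0.24 (-0.18 to 0.54). Each of these intervals held 0, so no difference of the medians was detectable at this depth. Of 15 TGF-beta members, 3 were higher and 2 lower, so they went both ways. Of 8 FGF members, 0 were higher and 1 lower, of 6 Notch members 1 and 0, of 11 epsin and clathrin genes 1 and 1, and of 3 VEGF members 0 and 0.

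Smooth muscle cells kept near-equal contractile genes and had lower heat shock genes in the double knockout. The comparison took 1516 and 4348 cells. The 14 contractile genes had a median of -0.03 (-0.05 to -0.02), none met the rule of size, and the sign turned, to 0.05, in cells thinned to 1000 UMIs. The intermediate filament gene Des stood at 0.52 and the actin-binding Cnn1 at -0.37. Of 11 heat shock genes, 8 were lower, with a median of -0.76 (-0.83 to -0.67). Hspa1b was 5.77-fold (5.46 to 6.09), Dnajb1 5.08-fold (4.71 to 5.50) and Hspa1a 3.75-fold lower (3.60 to 3.92). Interferon response genes had a median of 0.90 (0.56 to 1.15), led by Ifit3 and Ifi27l2a. Apoptosis genes had a median of 0.48 (0.40 to 0.56), led by Bbc3 at 5.28-fold and the tumour suppressor Trp53 at 2.76-fold. ER stress genes had a median of 0.38 (0.25 to 0.53), in which Sdf2l1 and Pdia3 were 3.16-fold and 1.88-fold higher and the stress factor Atf3 lower, at a log2 ratio of -0.87.

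The highest ranked genes of smooth muscle were Lars2 at 6.23-fold (5.75 to 6.76), Ccdc85b at 5.39-fold, the cysteine dioxygenase Cdo1 at 4.90-fold and the small heat shock protein Hspb7 at 4.55-fold. Lars2 and Ccdc85b were among the leading genes of cluster 0, behind Gm42418 and AY036118. Lars2 stood with those loci among the leading genes of clusters 2 and 4 too. Cluster 0 held 94 of 1536 Apoe knockout and 1099 of 4407 double knockout cells of the SMC class. Its median depth was 1750.5 UMIs in the Apoe knockout and 637 in the double knockout. A shift between clusters was thus not separated from a change within cells. Ier2 was 3.98-fold and the interferon regulatory factor Irf1 3.50-fold higher. The lowest included genes of other cells: Col2a1 had 902 UMIs in the Apoe knockout and 1 in the double knockout, a 578-fold lower level with an interval of 103 to 22835, and stood at 5813 CPM in Apoe knockout cluster 10. Lum and Dcn were 5.75-fold and 5.55-fold lower, at 89.1 and 108 CPM in Apoe knockout smooth muscle. Class II antigen presentation genes, which macrophages express, had a median of -2.32 (-2.89 to -1.72), led by Cd74, H2-Aa and H2-Eb1. The cartilage list had a median of -0.66 (-1.09 to -0.53). Endothelial identity genes had a median of 0.97 (0.33 to 1.64) in smooth muscle, but -0.11 in cells with at least 1000 UMIs and under 10% mitochondrial UMIs.

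Cells of the deposited fibroblast class had lower matrix genes in the double knockout, with 99 Apoe knockout and 55 double knockout cells. The name was not borne out by markers: the 10 leading genes of cluster 14 held 0 fibroblast markers, and Dcn stood at 147 CPM in Apoe knockout cells of the class, against 6322 CPM in the modEC class. In the new clustering, 123 Apoe knockout cells with this as their most common class were pericyte-like with Rgs5, Kcnj8 and Abcc9. The double knockout cluster with this most common class, of 57 cells, stayed unnamed. Of 18 extracellular matrix genes, 12 were lower and 0 higher, with a median of -0.70 (-0.92 to -0.58). Lum was 4.97-fold lower (2.66 to 10.5), and Fbln1, Col5a1 and Col3a1 had log2 ratios of -1.53, -1.30 and -1.29. Mesenchymal transition genes had a median of -0.66 (-0.84 to -0.38), with 7 of 14 lower, and mitochondrially encoded genes -0.76 (-0.85 to -0.71), with 8 of 12 lower. The retinol carrier Rbp4 was 18.8-fold higher (12.0 to 30.5), the stress phosphatase subunit Ppp1r15a 4.89-fold, Ier2 3.63-fold, the growth arrest gene Gadd45b 3.27-fold, the NF-kappa-B inhibitor Nfkbia 3.24-fold and Cdo1 3.17-fold. Hspa1b was 5.04-fold lower, Dnajb1 4.80-fold, the growth factor Gdf10 4.08-fold, the chemokine Cxcl12 3.91-fold and Tceal9 3.79-fold. Apoptosis genes had a median of 0.75 (0.16 to 0.95).

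Macrophages of cluster 13 had lower foamy macrophage, class II and cytokine genes in the double knockout and higher smooth muscle genes. There were 144 Apoe knockout cells with 864960 UMIs and 53 double knockout cells with 48818. The 12 foamy macrophage genes had a median of -1.84 (-2.18 to -1.54), with 9 lower. The lipid chaperone Fabp5 had a log2 ratio of -4.00, the lectin Lgals3 -2.65, Gpnmb -2.26 and the lipid droplet gene Plin2 -2.25. In the separate list of lipid uptake and storage, 4 of 11 genes were lower and 2 higher. The median was -2.41 (-2.68 to -1.83) for class II genes and at or below -1.97 for inflammatory cytokines, with Ccl4 at -3.12. Contractile genes had a median of 1.38 (1.20 to 1.55), with 12 of 13 higher, and stood at 24.5% of their smooth muscle level in the Apoe knockout and 65.9% in the double knockout. Weighting each cell equally gave a foamy median of -0.997. The general myeloid gene Lyz2 was lower too, at 4885 and 1905 CPM. A larger share of smooth muscle RNA lowers the CPM of macrophage genes, so part of these differences can come from it. The foamy median kept its direction after subtraction of a smooth muscle profile.

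The highest genes of cluster 13 were Ier2 at 6.50-fold, Fmo2 at 6.13-fold, Ccn3 at 5.64-fold, the differentiation inhibitor Id1 at 5.52-fold, Mylk4 at 5.32-fold and the matrix Gla protein gene Mgp at 4.86-fold. Fmo2, Ccn3 and Mgp stood at 1627, 935 and 11082 CPM in double knockout smooth muscle. Ier2, Id1 and Mylk4 stood there at 481, 402 and 653 CPM, so free smooth muscle RNA can bring part of each of these genes. In double knockout cluster 13, Mgp stood at 13765 CPM (12744 to 14847), above its smooth muscle level, so that RNA alone does not account for it. Ier2, Id1 and Mylk4 stood at 594, 492 and 676 CPM in those cells, with intervals that held the smooth muscle values. The 6 lowest had 0 UMIs in the double knockout: the interferon-induced chemokine Cxcl10 was at least 9.90-fold lower, Tnfaip2 at least 5.72-fold, Arl4c at least 3.48-fold, Col2a1 at least 3.39-fold, Cpd at least 3.16-fold and the antiviral gene Rsad2 at least 3.07-fold.

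The clusters named modEC by the authors differed in different ways. In cluster 7, with 92 and 308 cells, 11 of 19 extracellular matrix genes were lower, with a median of -0.86 (-0.98 to -0.56), and the 7 measured cell cycle genes were lower, with a median of -3.14 (-3.79 to -1.94). The proliferation genes Mki67 and Top2a had 61 and 73 UMIs in the Apoe knockout and 1 and 4 in the double knockout. Both were among the leading genes of cluster 7, so a different mix of cells in it was not separated from a change within cells. The heat shock median was -1.27 (-1.43 to -0.99), with Dnajb1 11.7-fold, Hspa1b 9.46-fold and Hspa1a 6.28-fold lower. Lum was 11.3-fold lower, the serpin gene Serpina3n 6.52-fold and Map3k7cl 4.07-fold. Lars2 was 5.35-fold, Ier2 4.63-fold, Cdo1 4.32-fold, Irf1 3.65-fold, Hspb7 3.54-fold and Eva1b 3.39-fold higher.

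In cluster 8, with 182 and 147 cells, the cartilage list had a median of -2.69 (-2.91 to -1.61) and extracellular matrix genes -0.86 (-1.28 to -0.74). Col2a1 had 4548 UMIs in the Apoe knockout and 0 in the double knockout, at least 203-fold lower, and Ibsp 3473 and 0, at least 155-fold lower. Chil1, Col11a2 and Slurp1 were at least 28.7-fold, 10.8-fold and 9.12-fold lower, and Chad had 471 and 1 UMIs, 63.1-fold lower with an interval of 11.3 to 2499. Slurp1 was the first of the leading genes of cluster 8, so there too unlike cells between libraries were not separated from a change within cells. The insulin-like growth factor binding protein Igfbp5 was 14.1-fold higher (9.94 to 20.1), Lars2 7.67-fold, Cdo1 4.58-fold, the laminin chain gene Lamc3 4.13-fold, the respiratory chain gene Cox5a 3.66-fold and Irf1 3.44-fold. Leukocyte adhesion and chemokine genes had a median of 0.69 (0.39 to 0.84), with the chemokine Ccl5 at 4 and 82 UMIs, and inflammatory cytokines 0.76 (0.30 to 0.99). Interferon response genes had a median of 1.43 (0.54 to 1.82), with Ifit2 at 3.98-fold.

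In cluster 10, with 164 and 90 cells, the double knockout cells lacked the cartilage genes by which the cluster is known, so its cells were not alike between libraries. Chad, Acan, Chil1, Fmod, Snorc and the cartilage regulator Sox9 had 0 UMIs in the double knockout and were lower by bounds from at least 9.23-fold, for Sox9, to at least 52.2-fold, for Chad. The cartilage list had a median at or below -3.38, extracellular matrix genes -1.22 (-1.64 to -0.89) and smooth muscle modulation genes -1.17 (-1.53 to -0.93). The cartilage median was at or below -1.41 with thinned cells, of which the double knockout kept 10. Lars2 was 5.16-fold, Ifitm3 3.58-fold, Tmem47 3.38-fold, the ferritin chain gene Fth1 3.33-fold, Vcam1 3.32-fold and Selenom 2.86-fold higher. Contractile genes had a median of 0.57 (0.40 to 0.67) and stood at 47.1% and 73.6% of their smooth muscle level.

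**Figure D4:**
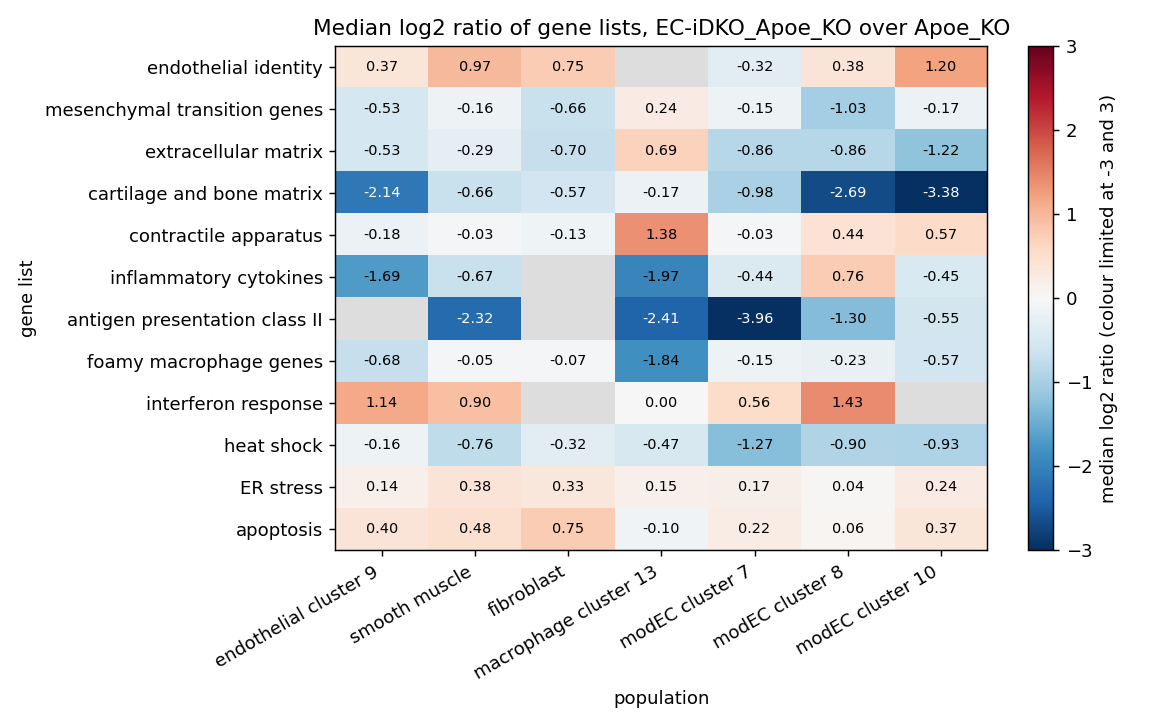
Median log2 ratio of 12 gene lists (vertical axis), double knockout over Apoe knockout, in the 7 populations (horizontal axis); grey marks lists with under 3 measured members. The heat shock medians were below 0 in all 7 populations, from -1.27 in cluster 7 to -0.16 in cluster 9, but 1.08 in cluster 9 and 0.76 in the fibroblast class after subtraction of smooth muscle RNA, and contractile genes ran from -0.18 in cluster 9 to 1.38 in cluster 13.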

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

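Of the tests below, those of carry-over between clusters, of a different dissection, of an influence on the whole library and of free smooth muscle RNA were chosen only after the result was seen. The settings behind the tests of depth and of dilution over the whole libraries were also chosen after the data were seen.

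Some gene lists stood out because their medians went opposite ways in a pair of populations, differences that were not tested. Extracellular matrix genes had a median log2 ratio of 0.69 in macrophage cluster 13 and -1.22 in modEC cluster 10, but -0.22 in cluster 13 with cells thinned to 1000 UMIs. Inflammatory cytokines stood at 0.76 in modEC cluster 8 and at or below -1.97 in macrophage cluster 13. Immediate early genes stood at 0.69 in macrophage cluster 13 and -0.73 in modEC cluster 10.

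Signals were also found in clusters that no comparison used. In cluster 15, Cfd had 2901 UMIs and Adipoq 157 in the double knockout, and each had 0 in the Apoe knockout. In cluster 20, the T cell receptor genes Cd3e and Trac had 29 UMIs each in the Apoe knockout and 0 in the double knockout. In cluster 19, the semaphorin gene Sema3g had 91 UMIs in the double knockout and 0 in the Apoe knockout.

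The first pattern was the higher matrix genes of Apoe knockout endothelial cluster 9. With cells thinned to 1000 UMIs, the median log2 ratio of Dcn, Lum, Col1a1, Col1a2 and Col3a1 was -2.84 (-3.39 to -2.10). The difference was thus present among the deeper cells. That value cannot decide on lower depth of the double knockout cells, because thinning does not alter the expected CPM ratio of the cells kept. It also dropped shallow cells unevenly, keeping 94 of 96 Apoe knockout and 59 of 287 double knockout cells. Carry-over of RNA from the matrix-rich clusters 8 or 10 could not be excluded. Scaled to the share that Dcn and Lum give, the median observed over predicted level of 5 cartilage genes was 0.548 (0.418 to 0.755) with cluster 8 as the source and 0.102 with cluster 10. The genotype stays open as untested, as does any difference between the preparations, since both coincide with the library.

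The second pattern was the near loss of cartilage and macrophage genes over the whole double knockout library. The median log2 ratio was at or below -2.47 after thinning and at or below -2.49 in cells with at least 2000 UMIs. Neither value can decide on depth or on dilution by smooth muscle RNA in shallow droplets, because shallow cells were dropped unevenly. Thinning kept 15 of 53 double knockout cells in cluster 13, 10 of 90 in cluster 10 and 1500 of 4348 in smooth muscle. At 2000 UMIs, 3 double knockout cells of cluster 13 and 773 of smooth muscle were left. A different piece of tissue in the dissections may account for part of the near loss. The adipocyte markers were at least 148-fold higher in the double knockout, and such fat surrounds the vessel. Fat cells in the digest do not show that less plaque was taken. The genotype remains open, untested, and cannot be told apart from the dissection with 1 library each.

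The third pattern was the lower heat shock genes. The median and its interval lay below 0 in 7 of 7 populations, but that count restates the pattern, so an influence on the whole library, such as handling or batch, was neither supported nor excluded. Smooth muscle RNA free in the suspension was argued against in cluster 7, where the median of -1.27 (-1.43 to -0.99) lay below that of smooth muscle itself, -0.76. Of the other 5 populations, 0 had an interval wholly below that of smooth muscle, so there free RNA could not be excluded, and its subtraction gave 1.08 in cluster 9 and 0.76 in the fibroblast class. Handling and genotype cannot be told apart, because each genotype had 1 library.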

How the results depend on the processing

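The subtraction of a smooth muscle profile, the whole deposited classes, smooth muscle without clusters 1, 5 and 18, the keeping of both copies of each cell, and the settings for whole-library markers were chosen only after the data were seen; the other settings were planned. Of 2374 alternative values over all results computed, every list in every population included, 1927 moved by less than their counting interval, 425 moved by more and 22 reversed, and the cause was not tested. Of the 96 named genes, 96 kept their direction with median-ratio scaling, equal weights for cells, cells with at least 1000 UMIs and under 10% mitochondrial UMIs, or a total without mitochondrial and ribosomal genes. Median-ratio scaling and the changed total shift all genes of a population by the same small amount, so they could not turn ratios this extreme. Thinned to 1000 UMIs, 90 kept it, 5 came to 0 and 1 reversed. List medians changed sign or came to 0 more often, in 183 of 1664 values, 160 of them for lists whose interval held 0, which are not counted as reversed; of the rest, 4 came to 0 and 19 reversed. They did so in 43 of 180 after subtraction of smooth muscle, 34 of 157 thinned, 32 of 204 in cells with at least 1000 UMIs and under 10% mitochondrial UMIs, and 30 of 213 with equal weights. Which genes rank highest and lowest depends on the minimum: at 20 UMIs in place of 100, 4 of the 24 ranked genes of cluster 9 were ranked again, 12 of 12 in smooth muscle, 2 of 12 in the fibroblast class, 8 of 12 in cluster 8 and 6 of 12 in each of clusters 7, 10 and 13. With a ratio of 2 in the rule of size, all ranked genes still met it. That follows from their selection by extreme ratios, the mildest being Egfl7 in cluster 9 at 2.31-fold, and is no check on them. Settings with doublets left out were not run, since Scrublet marked 4 and 0 cells. The depth of the double knockout, with 59 of 287 endothelial and 10 of 90 cluster 10 cells left after thinning, limits those medians. Medians of the adipocyte, T cell, macrophage and cluster 10 cartilage lists are bounds in each setting, since genes with 0 UMIs in 1 library set them.

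All medians below are log2 ratios. In cells with at least 1000 UMIs and under 10% mitochondrial UMIs, the cluster 9 medians were 1.17 for endothelial identity and -0.73 for mesenchymal genes, against 0.37 and -0.53. Smooth muscle contractile genes stood at -0.016, foamy genes at -2.41 and cluster 10 cartilage genes at -2.59. Reversed there were endothelial identity in smooth muscle (-0.11) and mitochondrially encoded genes in cluster 13 (-0.093) and cluster 7 (0.039). The shares of EC, SMC and fibroblast cells differed by -0.057, 19.6 and -1.50 percentage points, against 1.53, 17.0 and -3.08, and the ratio of median depths was 2.56.

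Thinned to 1000 UMIs, the medians were 1.05 for identity in cluster 9, 0.045 for smooth muscle contractile genes (reversed), -1.03 for fibroblast matrix and -1.41 for cluster 10 cartilage. Reversed were also Ctla2a in cluster 9 (0.58), contractile genes in the fibroblast class (0.11), and matrix (-0.22) and mitochondrially encoded genes (-0.046) in cluster 13. So were mesenchymal genes in cluster 7 (0.045) and FGF signalling in cluster 10 (0.52). With members of at least 100 UMIs, identity in cluster 9 was 1.05. Reversed were cartilage genes in cluster 9 (0.64), ER stress in the fibroblast class (-0.0099), and mesenchymal (0.064) and modulation genes (0.12) in cluster 7. Leaving out genes below 10% of their level in another class also gave 0.64 for cartilage genes in cluster 9.

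Equal weights for cells gave -0.997 for foamy genes and -2.70 for cluster 10 cartilage. Smooth muscle contractile genes stood at -0.059 with median-ratio scaling and -0.051 without mitochondrial and ribosomal genes in the total. After subtraction of smooth muscle, identity in cluster 9 was 0.19, mesenchymal genes -1.81, fibroblast matrix -1.13, foamy genes -1.28, cluster 7 matrix -1.25 and cluster 10 cartilage -3.94. Reversed there were contractile (1.01) and heat shock genes (1.08) in cluster 9 and the same lists in the fibroblast class (0.20 and 0.76). Mitochondrially encoded genes in cluster 7 (0.051) were reversed too. The contractile genes scale the subtraction, and some are on the mesenchymal list, so the contractile and mesenchymal values follow in part from the procedure. The whole EC class gave 1.13 for identity and -0.78 for mesenchymal genes.

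With endothelial cells out of the denominator, the SMC shares differed by 19.4 points. The new clustering gave 5.14 points for cells named fibroblast (reversed) and -11.6 for modEC. Both values rest on the naming: Apoe knockout clusters with the shared marker Lum were named modulated smooth muscle and counted as modEC. Without thinning, the shares of cluster 9 cells with a UMI differed by -4.18 points for Acta2, -63.5 for Col1a1, -54.1 for Col1a2 and -33.1 for Fn1, against -14.2, -47.5, -35.0 and -4.15. Thinned to 2000 UMIs, which kept 57 Apoe knockout and 8 double knockout cells, they differed by -25.0 for Tagln and -70.0 for Col1a2; the double knockout shares were 6 of 8 (34.9 to 96.8%) and 1 of 8 cells (0.316 to 52.7%).

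For whole-library markers, cells with at least 1000 UMIs and under 10% mitochondrial UMIs gave -1.96 for T cell, 5.63 for adipocyte and -1.16 for modulated smooth muscle genes. Cells with at least 2000 UMIs gave -0.72 for T cell, 8.003 for adipocyte, 0.58 for endothelial, -1.27 for modulated and -1.58 for cycling genes. Thinning gave -2.87 for macrophage, -2.02 for T cell, 3.73 for adipocyte, 0.88 for endothelial, -0.90 for modulated and -0.89 for fibroblast genes. Equal weights gave -4.17 for T cell, 5.28 for adipocyte, 1.07 for endothelial, -0.85 for modulated and -1.82 for cycling genes.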

Other observations

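Among the cells outside the comparisons, the double knockout held a larger share of an endothelial cluster, and fat cell transcripts that the Apoe knockout nearly lacked. Cluster 19 had 9 Apoe knockout and 67 double knockout cells, 0.371% and 1.22% of all cells, and the beads can set such a share. It led with Sema3g, Apold1, Cldn5 and Cdh5, genes of endothelial cells. Cluster 15 had 80 cells in each library, with 0 and 2901 UMIs of Cfd. In a new clustering, run on each library alone, 51 double knockout cells formed a cluster with 4 adipocyte markers, among them Adipoq and Plin1. In the Apoe knockout, 22 cells formed a cluster with 6 T cell markers, among them Cd3e and Lck, and the most common deposited class of these cells was EC. Over the whole libraries, the adipocyte markers were at least 148-fold higher in the double knockout.

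Erythroid transcripts were also unequal. Hbb-bs, a beta-globin gene, had 30 UMIs in the Apoe knockout and 340 in the double knockout, 22.0-fold higher (15.1 to 33.1) in CPM. In the double knockout, 94 cells formed a new cluster with 4 globin genes. Lars2 was among the highest ranked genes in 5 of the 7 populations. In the fibroblast class, where it was not ranked, it stood at 64.4 CPM in the Apoe knockout and 483 CPM in the double knockout. In macrophage cluster 13, where it was not ranked either, it stood at 64.7 and 471 CPM. Over the whole libraries, Lars2 was 6.20-fold higher (5.80 to 6.63) in the double knockout. The cause was not tested, and a technical one was not excluded.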
